A study of Homo sapiens with 18 samples.

How the data were processed

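Messenger RNA was sequenced in 18 libraries, 3 in each of 6 groups: Par with siCont, GemR with siCont and GemR with siSTIM1, each with vehicle or thapsigargin. Per the labels' protocols, RNA was taken with QIAzol and libraries were made from 500 ng with the TruSeq RNA Library Prep Kit v2. The submitters' processing notes name the hg38 genome, STAR 2.6.0c, HTSeq 0.11.1 and DESeq2; the gene annotation and any filter are not given in the sources used here.

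The authors deposited 1 table of normalized counts for all libraries, used here as a signal: gene read counts divided by 1 size factor per library, as the values themselves show, since all positive values of each column were whole multiples of its smallest step (100% within 0.01). The authors also deposited 5 tables of their own comparisons, with a log2 fold change and an adjusted p-value for each gene, per the file headers. The table of normalized counts held 26485 genes, of which 5873 were at 0 in all libraries and 28 had names turned into dates, and 0 mitochondrially encoded genes. Each column was matched to its sample by name, and 0 columns were left unused. Reads recovered from the steps ranged from 8922439 to 16519239 per library, and the 10 most abundant genes took 3.25% to 4.22% of the total. The values of siSTIM1 vehicle replicate 3 were whole multiples too, but its step of 0.993 lay too near 1 for a unit check. Count tests therefore left it out and used the other 17 libraries.

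From the deposited values, log2(normalized count + 1) was computed for the 13096 genes with a mean of at least 10, 20 of them under date names. A model with 1 mean per group was fitted over all 18 libraries with limma 3.58.1 (trend, 12 residual degrees of freedom) in R 4.3.3, and two-sided tests were made for 11 comparisons, 2 of them differences between thapsigargin responses. P-values were adjusted by Benjamini and Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The groups, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 21 lists covered the PERK-ATF4 response, ATF6-XBP1 chaperones and ERAD, calcineurin-NFAT targets, immediate early genes, NF-kB targets, calcium entry and stores, gemcitabine uptake and metabolism, sterol biosynthesis, epithelial and mesenchymal markers, classical and basal-like subtypes, S phase, G2/M, p53 targets, interferon-stimulated genes, hypoxia and glycolysis, fibroblast markers, immune and endothelial markers, mitochondrially encoded genes, and neighbours of STIM1 and RRM1. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Named genes were STIM1 and RRM1, the 6 highest and 6 lowest log2 fold changes among calls whose groups did not overlap (in the differences between responses, among all calls) with a group mean of at least 50, and up to 4 called members of each list with the largest change, or up to 2 others as values. Not all genes the rule took are named.

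Gene positions, transcript lengths and 3' UTRs came from GENCODE 29 (GRCh38), in which 23798 of the table's symbols matched 1 gene. Overlaps of calls were set beside the number that independent lists of the same lengths give. On simulated data, made from the real means and 200 changed genes per run in 3 runs, the Par thapsigargin comparison of 13096 genes recovered 63.2%, 96.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale and called 32 unchanged genes in all. The difference between the GemR and Par responses recovered 30.3%, 84.6% and 100% and called 19. All changed genes had a mean of at least 50, so recovery of lower genes was not measured. The noise was drawn gene by gene, without a length trend shared by the genes of a library.

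The alternatives were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, median-centred and quantile-normalized values, limma without trend and with a robust prior, only the libraries compared, the replicate number as a block, each replicate left out, a 2-fold minimum, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on 17 libraries, and 2 added after the data were seen: GemR siCont vehicle replicate 1 and GemR siSTIM1 thapsigargin replicate 1 left out together, the libraries whose deviations fell most with transcript length, and a term for each library's slope on transcript length. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.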

Results

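The series measured polyadenylated RNA by sequencing in L3.6pl, a human pancreatic cancer cell line, here called Par, and in a gemcitabine-resistant derivative called GemR that was kept in 64 nM gemcitabine. Par cells received a control siRNA (siCont), and GemR cells received either siCont or an siRNA against STIM1 (siSTIM1) for 48 h. For the last 3 h the cells were given DMSO (vehicle) or 500 nM thapsigargin, an inhibitor of the SERCA pump that empties the calcium store of the endoplasmic reticulum (ER). The 6 resulting groups held 3 libraries each, 18 in all. Reads recovered from the deposited values ranged from 8922439 to 16519239 per library, and 13096 of the 26485 genes in the table were tested. Values after ± are standard errors of limma's fit for log2 fold changes and standard deviations (n = 3) for normalized counts, and every adjusted p is from limma unless another method is named. The p-values measured the spread between these libraries, since the labels give replicate numbers and nothing on whether the replicates were separate cultures. Only GemR, a single derivative, is labelled as kept in gemcitabine. Resistance, exposure to the drug and other differences between GemR and Par therefore cannot be told apart.

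STIM1, the ER calcium sensor that opens plasma membrane calcium channels when the store is empty, was the siRNA target and was read first. Its mean normalized count was 457 ± 20.6 in Par with vehicle and 5890 ± 793 in GemR siCont with vehicle, a difference of 3.68 ± 0.10 on the log2 scale (12.8-fold, adjusted p = 5.1e-16). In GemR siSTIM1 with vehicle the mean was 382 ± 23.7, lower than in siCont by 15.3-fold (log2 fold change -3.93 ± 0.10, adjusted p = 7.2e-16). The knockdown left STIM1 near the level of Par. With thapsigargin the means were 431 ± 15.1 in Par, 6187 ± 115 in GemR siCont and 310 ± 40.8 in GemR siSTIM1. The 18 libraries all stood on the side that their labels name. RRM1, the gene next to STIM1, encodes the large subunit of ribonucleotide reductase, an enzyme that gemcitabine inhibits. Its count rose from 2979 ± 99.7 in Par to 53270 ± 2272 in GemR siCont with vehicle (17.9-fold, log2 fold change 4.16 ± 0.06, adjusted p = 2.4e-20). In siSTIM1 with vehicle the mean was 57784 ± 2218 (0.12 ± 0.06 against siCont, adjusted p = 0.114). The difference passed by quantile normalization (0.31, adjusted p = 0.00159) and by DESeq2 (0.15, adjusted p = 0.0452), the latter without siSTIM1 vehicle replicate 3. With thapsigargin RRM1 was higher in siSTIM1 than in siCont (0.19 ± 0.06, adjusted p = 0.0155), at 0.0631 without siCont thapsigargin replicate 1 and 0.0875 without siSTIM1 thapsigargin replicate 2. The thapsigargin log2 fold change against vehicle of STIM1 was -0.09 ± 0.10 in Par, 0.08 ± 0.10 in GemR siCont and -0.31 ± 0.10 in GemR siSTIM1. That of RRM1 was -0.19 ± 0.06, -0.28 ± 0.06 and -0.21 ± 0.06. Of these, RRM1 in GemR siCont (adjusted p = 0.00089) passed the threshold whichever library was left out. STIM1 in GemR siSTIM1 (adjusted p = 0.022) had adjusted p = 0.0718 and 0.0880 without vehicle replicates 1 and 3, and 0.128 and 0.0615 without thapsigargin replicates 1 and 3. RRM1 in GemR siSTIM1 (adjusted p = 0.012) had 0.0566 without vehicle replicate 1 and 0.0646 without thapsigargin replicate 1. RRM1 in Par (adjusted p = 0.016) had 0.0517 and 0.0620 without vehicle replicates 1 and 3, and 0.0638 and 0.0521 without thapsigargin replicates 2 and 3.

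**Figure D1:**
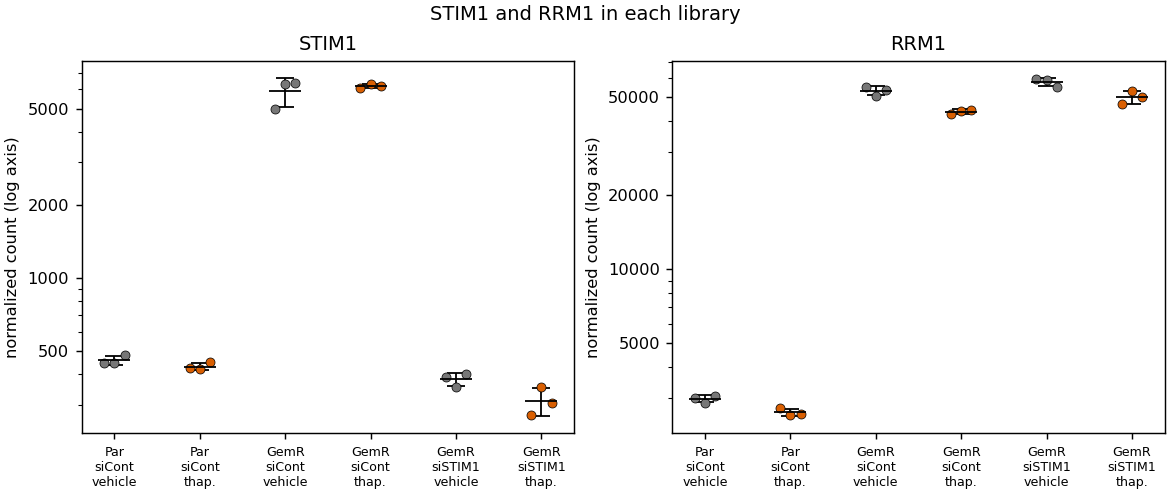
Normalized counts of STIM1 (left) and RRM1 (right) on log axes in the 6 groups; each point is a library (grey vehicle, orange thapsigargin), the long bar is the group mean and the whiskers are 1 SD (n = 3). STIM1 was high in GemR siCont alone, at means of 5890 and 6187, while RRM1 was high in all GemR groups, at means between 43791 and 57784.

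In Par cells, 3 h of thapsigargin set off the ER stress program. CHAC1, a glutathione-degrading enzyme under ATF4, rose 126-fold, from 24.3 ± 3.53 to 3163 ± 166 normalized counts (log2 fold change 6.97 ± 0.11, adjusted p = 9.9e-20). DDIT3, the stress transcription factor CHOP, rose by 5.29 ± 0.12 and the ATF4 target SESN2 by 5.12 ± 0.13 on the log2 scale. HERPUD1, which takes part in ER-associated degradation, rose by 4.94 ± 0.06, and HSPA5, the main ER chaperone, by 2.79 ± 0.06, from 15414 ± 439 to 106848 ± 4069 normalized counts. IL1A (4.85 ± 0.51), CXCL2 (3.73 ± 0.28), NR4A3 (3.86 ± 0.22) and ATF3 (4.41 ± 0.16) rose with them. The strongest falls were in FAM111B (-3.57 ± 0.12), SPRY1, an inhibitor of receptor tyrosine kinase signalling (-2.94 ± 0.16), the growth factor BMP4 (-2.82 ± 0.16), the heat shock gene HSPA1A (-2.39 ± 0.08, uncertain beside its near-identical copy HSPA1B) and the transcription factor SOX2 (-2.32 ± 0.26).

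Among the 30 PERK-ATF4 genes 29 rose and 1 fell in Par, with the same counts when adjusted over the list alone, and the median was 1.64 (camera adjusted p = 4.1e-33). Of 29 ATF6-XBP1 chaperone and ERAD genes 28 rose and none fell (28 and 0 adjusted over the list alone; adjusted p = 3.6e-30). Calcineurin-NFAT targets, which read out calcium signalling, rose in 10 of 14 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 2.2e-08), and immediate early genes in 19 of 21 (19 and 1 lower adjusted over the list alone; adjusted p = 2.0e-12). NF-kB targets rose in 12 of 17 with none lower, also 12 adjusted over the list alone, at an adjusted p of 1.8e-07 that became adjusted p = 0.0616 with an estimated correlation. Sterol biosynthesis genes rose in 16 of 20 (17 and 1 lower adjusted over the list alone; adjusted p = 8.4e-09), led by STARD4 (1.996 ± 0.12) and HMGCS1 (1.69 ± 0.08). S phase genes fell in 16 of 20 with CDC6 higher (17 lower and 1 higher adjusted over the list alone; adjusted p = 2.2e-08), and G2/M genes fell in 10 of 20, again 10 adjusted over the list alone (adjusted p = 0.00020, and adjusted p = 0.138 with an estimated correlation). In all, 5253 genes passed an adjusted p of 0.05, 2679 higher and 2574 lower, and 833 of them changed at least 2-fold.

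GemR cells with the control siRNA answered thapsigargin with the same stress lists and with strong changes in calcium-responsive genes. RRAD, a small GTPase that inhibits calcium channels, rose 60.3-fold (log2 fold change 5.91 ± 0.30, adjusted p = 9.4e-12). The nuclear receptor NR4A2 rose by 5.22 ± 0.17, from 37.8 ± 12.3 to 1396 ± 74.7 normalized counts. CHAC1 rose by 4.82 ± 0.11 and the tight junction gene CLDN4 by 4.46 ± 0.24. Of the NFAT list 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone; median 2.77, adjusted p = 1.4e-11), with NFATC2 at 4.17 ± 0.19 and PTGS2, the inducible cyclooxygenase, at 3.86 ± 0.13. The strongest falls were in the YAP target ANKRD1 (-3.24 ± 0.09), FAM111B (-2.81 ± 0.12), the vitamin D hydroxylase CYP24A1 (-2.47 ± 0.16) and E2F2, a cell cycle transcription factor (-2.44 ± 0.26).

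The PERK-ATF4 list had 26 genes higher and 1 lower of 30 in GemR siCont (26 and 1 adjusted over the list alone; median 1.02, adjusted p = 6.6e-24). The ATF6-XBP1 list had 28 of 29 higher (28 adjusted over the list alone; adjusted p = 4.1e-27). NF-kB targets rose in 13 of 17 (13 adjusted over the list alone; adjusted p = 1.4e-10), led by the chemokines CXCL3 (4.41 ± 0.25), CXCL2 (3.39 ± 0.28) and CXCL1 (2.90 ± 0.17). S phase genes fell in 19 of 20 and G2/M genes in 18 of 20, the same adjusted over the list alone (adjusted p = 7.9e-10 and 1.0e-10), with the mitotic kinase AURKA at -1.16 ± 0.07. Epithelial markers rose in 8 of 16 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0019), among them CDH1, the gene of E-cadherin (2.34 ± 0.14). Sterol genes rose in 14 of 20 (15 adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.0647 with an estimated correlation). Genes of p53 rose in 7 of 18 with 1 lower, the same adjusted over the list alone (adjusted p = 0.0103), with BBC3, which drives apoptosis, at 2.84 ± 0.21 and the cell cycle inhibitor CDKN1A at 2.32 ± 0.14. The 4402 genes past the threshold were 2338 higher and 2064 lower, 771 of them by at least 2-fold, and 2843 passed when the 6 libraries were fitted on their own.

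GemR cells with STIM1 depleted still mounted the ER stress response. HERPUD1 rose by 4.58 ± 0.06, CHAC1 by 4.41 ± 0.11 and DDIT3 by 4.32 ± 0.12 on the log2 scale, and 29 of 30 PERK-ATF4 genes rose with 1 lower (29 and 1 adjusted over the list alone; median 1.26, adjusted p = 3.0e-42). ATF6-XBP1 genes rose in 27 of 29 (28 adjusted over the list alone; adjusted p = 2.0e-40). NFAT targets rose in 12 of 14 (12 adjusted over the list alone; median 2.11, adjusted p = 1.3e-13), with RCAN1, a feedback inhibitor of calcineurin, at 3.53 ± 0.12 and NFATC2 at 3.25 ± 0.19. Immediate early genes rose in 15 of 21 (17 adjusted over the list alone; adjusted p = 2.6e-12), NR4A2 by 3.96 ± 0.17. Falls were led by SOX2 (-2.61 ± 0.26), the Wnt target AXIN2 (-2.45 ± 0.22), SPRY1 (-1.96 ± 0.16) and the transcription factor SOX4 (-1.89 ± 0.13). G2/M genes fell in 18 of 20, also 18 adjusted over the list alone (adjusted p = 2.6e-12). Genes of gemcitabine uptake and metabolism fell in 7 of 14, the same adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.0801 with an estimated correlation), among them the nucleoside transporters SLC29A1 (-0.65 ± 0.08) and SLC29A2 (-0.35 ± 0.08). The threshold was passed by 3187 genes, 1635 higher and 1552 lower, 545 by at least 2-fold.

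**Figure D2:**
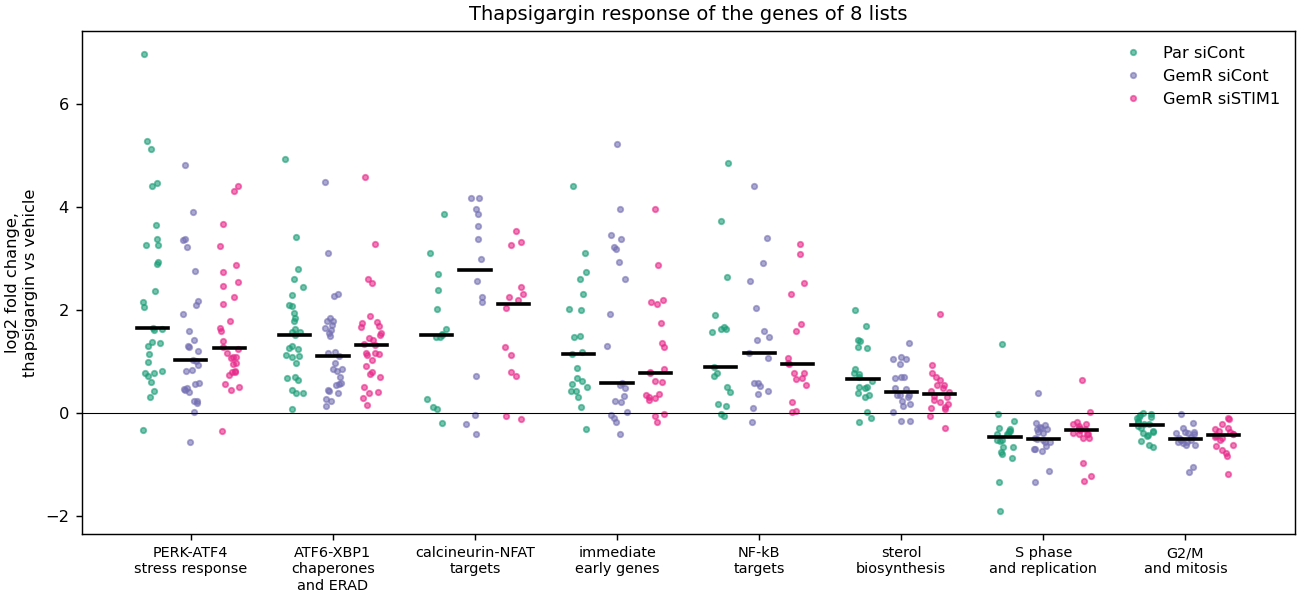
Log2 fold change of thapsigargin against vehicle (vertical axis) for the tested genes of 8 lists (horizontal axis) in Par siCont, GemR siCont and GemR siSTIM1; each point is a gene and each black bar the median of its list. The PERK-ATF4 median was 1.64 in Par, 1.02 in GemR siCont and 1.26 in GemR siSTIM1, while the calcineurin-NFAT median was 1.52, 2.77 and 2.11.

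The responses overlapped widely across genes, which are not independent replicates. Log2 fold changes correlated at Pearson's r = 0.64 and Spearman's rho = 0.58 between Par and GemR siCont, 0.73 and 0.54 between GemR siCont and GemR siSTIM1, and 0.69 and 0.55 between Par and GemR siSTIM1, pairs that shared no library. Par and GemR siCont had 1461 genes higher in both, against 478 for independent lists of the same lengths, and 1101 lower in both, against 406; 93.2% of the genes past the threshold in both had the same direction. For GemR siCont and GemR siSTIM1 these were 1236 against 292, 907 against 245, and 98.3%.

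The thapsigargin responses of GemR and Par differed in stress genes, which responded less in GemR, and in single genes such as RRAD and CLDN4, which responded more. The interaction was -2.16 ± 0.16 for CHAC1, -1.94 ± 0.16 for DDIT3 and -1.84 ± 0.12 for TRIB3, a pseudokinase under ATF4 and CHOP. Part of that of CHAC1 lay in vehicle, where its normalized count was 24.3 ± 3.53 in Par and 62.0 ± 5.37 in GemR siCont. With thapsigargin its counts were 3163 ± 166 and 1771 ± 83.3. In the list, 23 of 30 PERK-ATF4 genes were lower and none higher (25 lower adjusted over the list alone; median -0.64, adjusted p = 8.5e-25). ATF6-XBP1 genes were lower in 12 of 29 (16 adjusted over the list alone; median -0.32, adjusted p = 9.8e-08). The other way went RRAD (5.44 ± 0.43, adjusted p = 3.5e-08), CLDN4 (3.20 ± 0.34), the kinase SGK1 (2.97 ± 0.22), the transcription factor SOX9 (2.84 ± 0.18), the cytokine IL11 (2.72 ± 0.35), NFATC2 (2.64 ± 0.27) and RCAN1 (2.13 ± 0.17). CLDN4 went from 584.5 ± 132 to 1426 ± 447 normalized counts in Par and from 127 ± 51.4 to 2694 ± 412 in GemR siCont.

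NFAT targets as a list had a larger response in GemR, 7 of 14 higher and 2 lower, also 7 and 2 adjusted over the list alone (median 0.89, adjusted p = 0.0015), and the p did not pass with an estimated correlation (adjusted p = 0.213). The 2 lower members included the growth response factor EGR2 (-2.43 ± 0.30). The interaction was also negative for EGR1 (-2.50 ± 0.12, adjusted p = 8.4e-11), IL1A (-4.27 ± 0.73) and the lipoprotein receptor OLR1 (-2.93 ± 0.31). For ANKRD1 it was -2.60 ± 0.12, a fall with thapsigargin that was larger in GemR siCont than in Par. Sterol genes were lower in 5 of 20 (6 adjusted over the list alone) and G2/M genes in 4 of 20 (5 adjusted over the list alone), at adjusted p = 0.0038 and 0.0016, and at adjusted p = 0.348 and 0.311 with an estimated correlation. The interaction was past the threshold for 1938 genes, 935 higher and 1003 lower in GemR, 438 of them by at least 2-fold. Without replicate 1 of GemR siCont vehicle, whose deviation from its group followed transcript length (Spearman's rho = -0.615 across 12446 genes), 2943 genes passed. The PERK-ATF4 median was then -0.62.

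**Figure D3:**
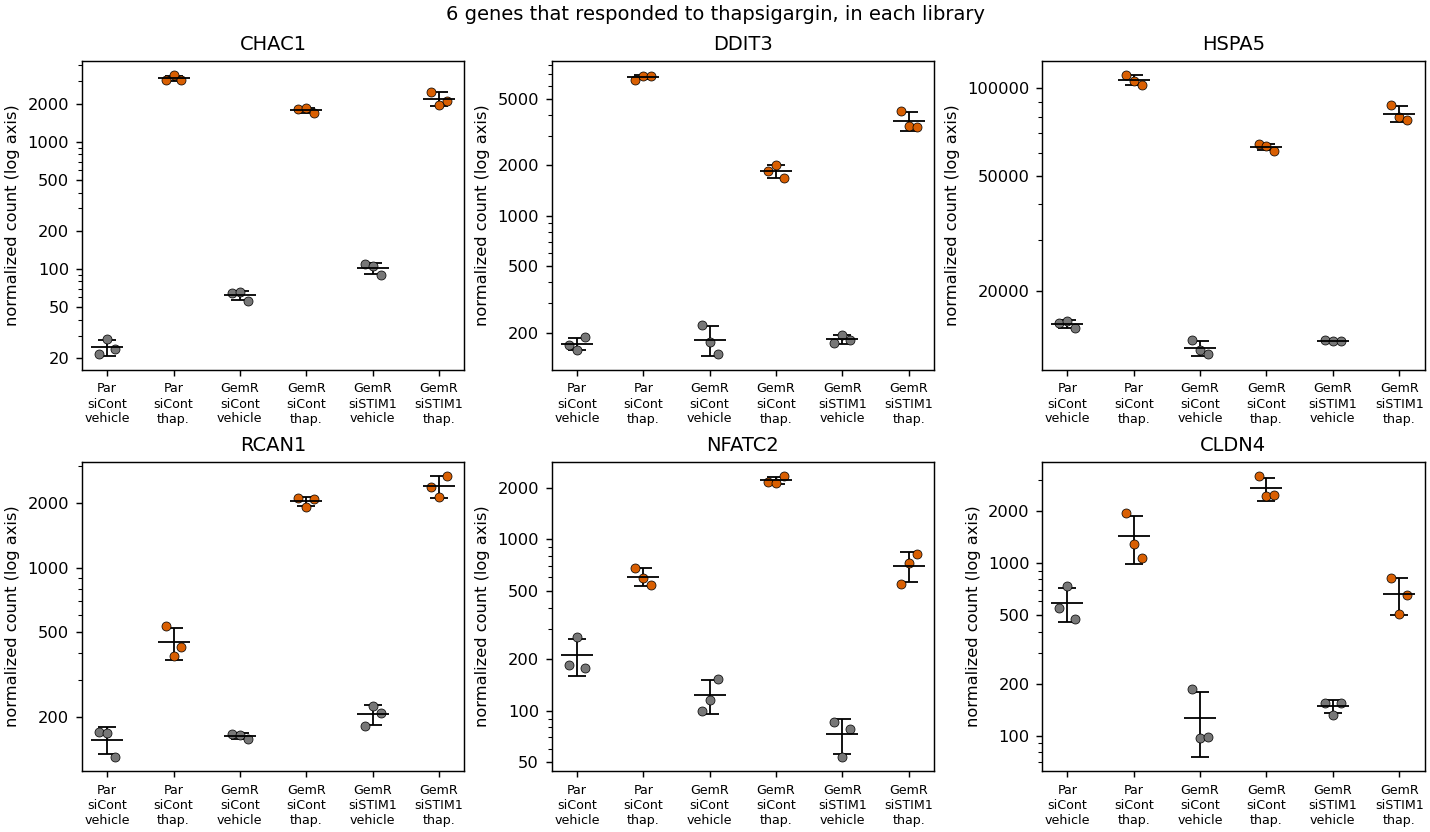
Normalized counts on log axes of 6 genes in the 6 groups; each point is a library (grey vehicle, orange thapsigargin), the long bar is the group mean and the whiskers are 1 SD (n = 3). With thapsigargin DDIT3 stood at a mean of 6732 in Par and 1849 in GemR siCont, and NFATC2 at 607 and 2209.

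In GemR cells with siSTIM1 part of the thapsigargin response was smaller than with siCont, and the PERK-ATF4 list responded somewhat more. CLDN4 rose less by -2.33 ± 0.34 (adjusted p = 0.00034), RRAD by -2.47 ± 0.43 (adjusted p = 0.0017) and LYPD3 by -2.65 ± 0.27 (adjusted p = 7.1e-06). CXCR4, a chemokine receptor, went from 92.3 ± 6.92 to 202 ± 25.7 normalized counts with siCont and from 193 ± 19.0 to 78.4 ± 4.54 with siSTIM1 (interaction -2.41 ± 0.16, adjusted p = 4.1e-08). The nuclear receptor NR4A1 (-2.09 ± 0.20), the immediate early gene FOS (-1.84 ± 0.20), PTGS2 (-1.41 ± 0.18) and NFATC1 (-1.45 ± 0.24) responded less, and DDIT3 (0.97 ± 0.16) and TRIB3 (0.82 ± 0.12) more, while CHAC1 (-0.41 ± 0.16), ATF3 (-0.35 ± 0.23) and SESN2 (-0.23 ± 0.19) did not pass. ANKRD1 (1.52 ± 0.12), PDE7B, a cyclic AMP phosphodiesterase (1.54 ± 0.15), and CYP24A1 (1.38 ± 0.22), which fell with thapsigargin in siCont, fell less in siSTIM1.

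By list, 12 of 30 PERK-ATF4 genes responded more with siSTIM1 and none less (13 and 1 adjusted over the list alone; median 0.25, adjusted p = 1.7e-08). Members with a smaller response were 4 of 14 NFAT targets with 1 larger (7 and 1 adjusted over the list alone; median -0.55) and 9 of 21 immediate early genes with 4 larger (10 and 4 adjusted over the list alone; median -0.35). Both lists had adjusted p = 0.0024, which became adjusted p = 0.136 and 0.455 with an estimated correlation. The p53 list had 3 of 18 lower, also 3 adjusted over the list alone (adjusted p = 0.0047). The hypoxia and glycolysis list had 5 of 17 lower, also 5 adjusted over the list alone (adjusted p = 0.0037, and adjusted p = 0.0763 with an estimated correlation). This interaction was past the threshold for 577 genes, 197 higher and 380 lower, 140 by at least 2-fold. The count depended on single libraries, with 323 without siSTIM1 vehicle replicate 1, 341 without siSTIM1 vehicle replicate 3, 372 without siSTIM1 thapsigargin replicate 1, 334 and 338 without siCont thapsigargin replicates 1 and 3, and 1216 without siCont vehicle replicate 3.

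GemR and Par cells differed widely in vehicle. PTGES, which makes prostaglandin E2, rose 47.2-fold in GemR, from 60.0 ± 5.56 to 2881 ± 244 normalized counts (log2 fold change 5.56 ± 0.10, adjusted p = 2.8e-18). The monoamine oxidase MAOA (4.38 ± 0.34) and the surface protein mesothelin, MSLN (3.84 ± 0.26), rose with it. The chemokine CXCL5 fell from 865 ± 75.8 to 4.16 ± 4.20 (log2 fold change -7.71 ± 0.46, adjusted p = 1.2e-10). ST6GALNAC1, a sialyltransferase, and the Wnt inhibitor DKK4 went to counts near 0 in GemR (-5.72 ± 0.44 and -5.70 ± 0.53), where the fold depends on the 1 added before the log, as it does for CXCL5. Collagen gene COL3A1 went from 7349 ± 287 to 174 ± 9.53 (-5.39 ± 0.12). Epithelial markers fell in 14 of 16 and none rose (14 adjusted over the list alone; median -0.92, adjusted p = 8.2e-10), with CLDN4 at -2.25 ± 0.24 and CLDN7 at -2.04 ± 0.12. Genes of the classical subtype of pancreatic ductal cancer fell in 6 of 10 and none rose (7 adjusted over the list alone; adjusted p = 6.4e-06), among them the transcription factor GATA6 (-2.05 ± 0.12).

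The mesenchymal list had 4 genes higher and 5 lower of 13 in vehicle (5 and 5 adjusted over the list alone; median 0.14, mean -0.07, test upwards at adjusted p = 0.758). The basal-like subtype list had 5 higher and 3 lower of 15, the same adjusted over the list alone (median 0.18, mean -0.07, test upwards at adjusted p = 0.518). ATF6-XBP1 genes were lower in 21 of 29 (22 adjusted over the list alone; median -0.34, adjusted p = 6.1e-07) before any thapsigargin. Of 16 interferon-stimulated genes 8 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.0788 with an estimated correlation). Of 20 sterol genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.338 with an estimated correlation). The list of calcium entry and store genes had 4 higher and 7 lower of 24 (5 and 7 adjusted over the list alone; median -0.10, mean 0.05, test downwards at adjusted p = 0.636), with STIM1 the member that changed most. The 5 tested fibroblast markers fell in 4 and rose in 1, ACTA2, the same adjusted over the list alone (adjusted p = 0.0027). Of 3 tested immune and endothelial markers CDH5 fell (-0.70 ± 0.19, also adjusted over the list alone), too few for the list test. Without Par vehicle replicate 3 CDH5 did not pass (-0.55). Of the mitochondrially encoded genes 0 were in the table. In all 5000 genes passed, 2365 higher and 2635 lower, 913 by at least 2-fold, and 3129 passed when the 6 libraries were fitted on their own.

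With thapsigargin the stress genes stood lower in GemR than in Par. PERK-ATF4 genes were lower in 27 of 30 and none higher (28 adjusted over the list alone; median -1.06, adjusted p = 1.0e-17), with FGF21 at -3.46 ± 0.34, TRIB3 at -2.34 ± 0.09 and DDIT3 at -1.87 ± 0.12. ATF6-XBP1 genes were lower in 28 of 29 (28 lower and 1 higher adjusted over the list alone; median -0.65, adjusted p = 2.3e-13). RRAD stood 35.5-fold higher in GemR (5.15 ± 0.30), IL11 17.4-fold higher (4.12 ± 0.25) and RCAN1 at 2.20 ± 0.12, while IL1A (-5.89 ± 0.51), OLR1 (-6.29 ± 0.22) and EPGN, a ligand of the EGF receptor (-5.50 ± 0.34), stood lower. G2/M genes were lower in 14 of 20 (15 adjusted over the list alone; adjusted p = 0.00038, and adjusted p = 0.167 with an estimated correlation). Past the threshold were 6314 genes, 3038 higher and 3276 lower, 1183 by at least 2-fold.

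The genes around STIM1 and RRM1 on chromosome 11p15.4 were higher in GemR from STIM1 on towards the centromere. All 18 tested genes between 3854527 and 6683401 (GRCh38), from STIM1 to the mitochondrial ribosome gene MRPL17, passed the threshold and were at least 2-fold higher in both media, at log2 fold changes of 1.67 to 4.16 in vehicle and 1.28 to 4.06 with thapsigargin. They included TRIM6 (4.02 ± 0.36), uncertain because it overlaps a readthrough gene, TRIM68 (2.74 ± 0.09) and, with thapsigargin, the Fc receptor TRIM21 (3.12 ± 0.08). On the other side of STIM1, 7 of the 11 tested genes within 1 Mb were lower in vehicle and none was higher, and with thapsigargin 7 were lower and 2 higher, CDKN1C (2.35 ± 0.30) and SLC22A18. Further on, between MRPL17 and ADM, 18 of 22 tested genes were higher in vehicle and none lower, 14 of them by at least 2-fold, and with thapsigargin 19 were higher and 1 lower. Of the genes beyond ADM that start under 12 Mb, none of 10 was higher and 5 were lower in vehicle, and 1 was higher and 6 lower with thapsigargin. Of the list of 11 tested neighbours fixed before the data were examined, which holds genes of both sides, 6 were higher and 4 lower in vehicle (6 and 5 adjusted over the list alone; adjusted p = 0.0023). With siSTIM1 the stretch from STIM1 to MRPL17 had a median change of -0.01 in vehicle and -0.05 with thapsigargin when STIM1 and RRM1 were left out, and TRIM6 in it, which holds the word GAATCTC in the 3' UTR, fell (-1.28 ± 0.36 and -2.09 ± 0.36). TRIM5 (0.33 ± 0.09) and TRIM68 (0.27 ± 0.09) rose in vehicle. MRPL17 and ADM were chosen as edges after their values had been seen, and whether reads were counted by strand is not given in the sources used here.

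**Figure D4:**
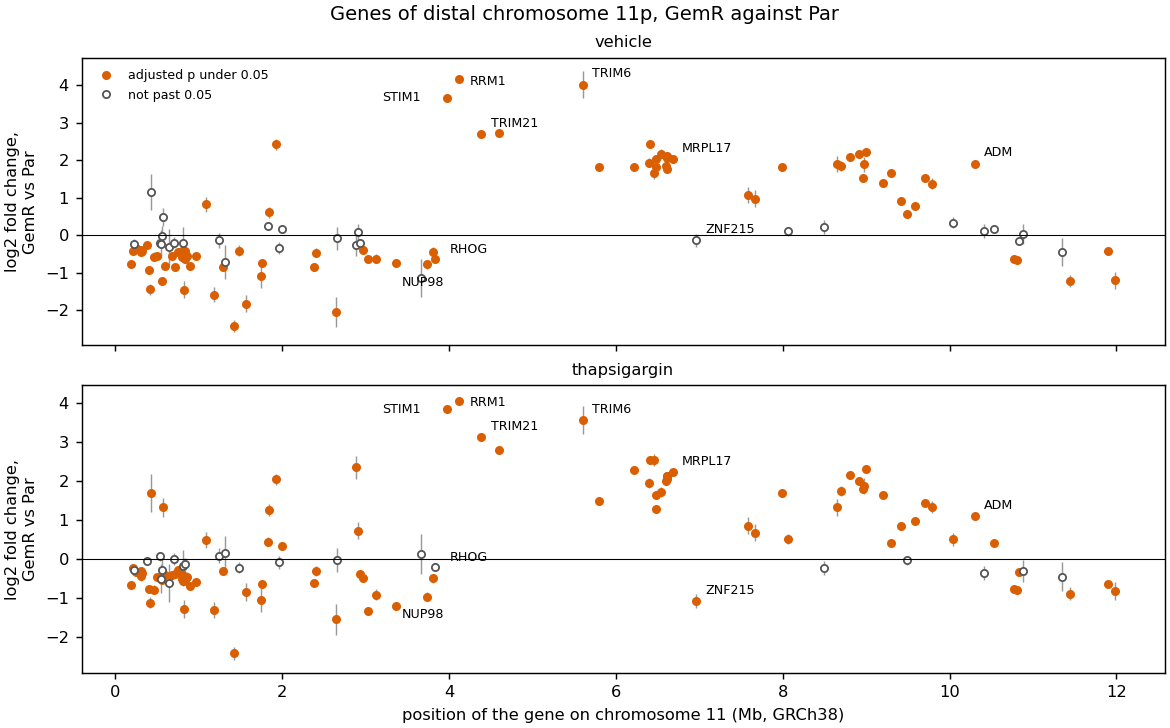
Log2 fold change of GemR siCont against Par siCont (vertical axis) by gene position on distal chromosome 11p (horizontal axis, Mb, GRCh38), in vehicle (top) and thapsigargin (bottom); each point is a tested gene, its whisker is 1 standard error, and filled points passed an adjusted p of 0.05. The step upwards lies between RHOG and STIM1 in both media, and the 18 tested genes from STIM1 to MRPL17 all lie above 1.

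In GemR cells without thapsigargin, genes of sterol synthesis and both chains of the amino acid transporter of SLC7A5 and SLC3A2 were lower with siSTIM1 than with siCont. Of 20 sterol genes 19 fell and none rose (20 adjusted over the list alone; median -0.68, adjusted p = 3.1e-12), led by INSIG1, a sensor of the sterol pathway (-1.83 ± 0.14), and STARD4, which carries cholesterol (-1.48 ± 0.12). SLC7A5, the large neutral amino acid transporter, fell 6.80-fold, from 49745 ± 9494 to 7220 ± 84.4 normalized counts (log2 fold change -2.77 ± 0.10, adjusted p = 3.4e-13). Its partner chain SLC3A2 fell by 1.85 ± 0.07 on the log2 scale. The matrix protease MMP10 fell from 61.3 ± 17.6 to 2.52 ± 1.83 (-4.24 ± 0.29), a fold that depends on the 1 added before the log. The keratin KRT6A also fell (-3.09 ± 0.23). Genes of the basal-like subtype fell in 11 of 15 with 1 higher (11 and 2 adjusted over the list alone; median -0.78, adjusted p = 6.3e-05). Secretogranin SCG2 rose from 48.2 ± 5.27 to 599.6 ± 40.9 (3.61 ± 0.11), and the peroxidase PXDN (3.20 ± 0.32), the netrin receptor UNC5A (3.03 ± 0.19), the matrix gene FN1 (2.38 ± 0.18) and CDH1 (1.59 ± 0.14) rose as well. Of 1015 genes with the 7-base word GAATCTC in the 3' UTR, SLC7A5 among them, 31.0% fell, against 21.2% of 10685 genes without it.

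Immediate early genes fell in 12 of 21 with 3 higher in vehicle, the same adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.512 with an estimated correlation), with EGR2 at -2.06 ± 0.21 and FOSB at -1.87 ± 0.21. Hypoxia and glycolysis genes fell in 10 of 17 with 2 higher, the same adjusted over the list alone (adjusted p = 0.0020, and adjusted p = 0.0630 with an estimated correlation), among them the glucose transporter SLC2A1 (-1.05 ± 0.08). ORAI3, a plasma membrane calcium channel, rose by 1.61 ± 0.15 in the list of calcium entry genes, of which 8 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.867). Past the threshold were 5496 genes, 2733 higher and 2763 lower, 662 by at least 2-fold, and 3294 passed when the 6 libraries were fitted on their own.

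With thapsigargin, siSTIM1 cells had lower NFAT and immediate early genes than siCont cells, beside the sterol genes. EGR3 was 11.2-fold lower (log2 fold change -3.48 ± 0.29, adjusted p = 2.4e-08), and FOSB (-3.17 ± 0.21), IL11 (-1.78 ± 0.25) and NFATC2 (-1.67 ± 0.19) were lower, of which FOSB and NFATC2 hold the word GAATCTC in the 3' UTR, while RCAN1 stood at 2404 ± 273 normalized counts against 2048 ± 101 in siCont. NFAT targets were lower in 10 of 14 with 1 higher, the same adjusted over the list alone (median -0.82, adjusted p = 0.00013, and adjusted p = 0.0575 with an estimated correlation). Immediate early genes were lower in 15 of 21 with 2 higher, the same adjusted over the list alone (adjusted p = 6.1e-07, and adjusted p = 0.146 with an estimated correlation). Sterol genes were lower in 19 of 20, also 19 adjusted over the list alone (median -0.81, adjusted p = 4.2e-13), INSIG1 at -2.45 ± 0.14. Hypoxia and glycolysis genes were lower in 13 of 17, also 13 adjusted over the list alone (adjusted p = 7.6e-07), with EGLN3 at -1.98 ± 0.14. Interferon-stimulated genes were higher in 9 of 16 with 2 lower, the same adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.0575 with an estimated correlation), IFIT3 by 1.39 ± 0.17. CYP24A1 stood 2.92 ± 0.16 higher and SCG2 3.94 ± 0.11 higher on the log2 scale. The count was 4796 genes, 2321 higher and 2475 lower, 728 by at least 2-fold.

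Across genes, the siSTIM1 change ran against the difference between GemR and Par weakly, and in 1 of the 2 pairings without a shared library. The vehicle difference of GemR and Par correlated with the siSTIM1 change under thapsigargin, with no shared library, at r = -0.0048 and rho = -0.0045 (covariance -0.0015), and 47.5% of the 2172 genes past the threshold in both moved the same way. Every combination of directions lay above independent lists here. Higher in both were 450 against 419, and lower in both 581 against 498. Higher in GemR and lower with siSTIM1 were 541 against 447, and the other way 600 against 467. In the other pairing without a shared library the values were r = -0.09, rho = -0.13 and covariance -0.032, and 37.2% of 2866 genes moved the same way. There 908 genes were higher in GemR and lower with siSTIM1, against 641 for independent lists, and 891 were lower in GemR and higher with siSTIM1, against 684. Higher in both were 520 against 634, and lower in both 547 against 691.

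Set against untreated Par cells, GemR cells with thapsigargin showed the stress response and the line difference together, with siCont and with siSTIM1. CHAC1 stood 6.14 ± 0.11 and 6.43 ± 0.11 higher on the log2 scale, PTGES 5.45 ± 0.10 and 5.33 ± 0.10 higher, and CXCL5 was lower, at -7.61 ± 0.46 and -8.97 ± 0.46, folds set by the added 1 at counts near 0. ATF6-XBP1 genes were higher in 23 of 29 with 1 lower and in 26 with 1 lower (24 and 1, and 26 and 1, adjusted over the list alone; adjusted p = 3.9e-12 and 4.5e-13). Sterol genes were higher in 18 of 20 with siCont, also 18 adjusted over the list alone (adjusted p = 1.5e-08), and with siSTIM1 6 were higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.702). Interferon-stimulated genes were higher in 12 of 16 with siSTIM1 and 2 lower (14 and 2 adjusted over the list alone; adjusted p = 0.00032), OASL by 2.99 ± 0.18. With siCont 6365 genes passed the threshold, 3169 higher and 3196 lower, 1466 by at least 2-fold, and with siSTIM1 7475 passed, 3672 higher and 3803 lower, 1865 by at least 2-fold.

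The authors' own tables, which cover 5 of these comparisons, hold 5158 genes under an adjusted p of 0.05 for Par, 4463 for GemR siCont, 3287 for GemR siSTIM1, and 6390 and 7629 against untreated Par. The counts shared with the calls given here were 4973, 4227, 3111, 6069 and 7194, all in the same direction.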

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

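The tests of scaling, STIM1 level, length bias, RNA mixing, reads of neighbouring genes, a gain on both sides of STIM1, the comparison of the pair of response differences and the comparison with equally swapped splits were chosen only after the result was seen. The results here are differences between thapsigargin responses in 2 groups, each past a test of the difference itself at the preset correlation for lists.

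Between GemR and Par 1938 genes differed in response. The largest positive differences on the log2 scale were in RRAD (5.44), CLDN4 (3.20), TMCC3 (3.07), SGK1 (2.97), SOX9 (2.84) and LYPD3 (2.76). The largest negative ones were in IL1A (-4.27), OLR1 (-2.93), INHBE (-2.68), ANKRD1 (-2.60), EGR1 (-2.50) and EGR2 (-2.43). A negative difference can be a smaller rise or a larger fall in GemR, and for ANKRD1 it was a larger fall. List medians were -0.64 for PERK-ATF4, -0.32 for ATF6-XBP1, 0.89 for calcineurin-NFAT targets, -0.27 for sterol biosynthesis, 0.49 for the classical subtype and -0.19 for G2/M. The classical subtype list had an adjusted p of 0.0172, which was 0.0749 without GemR siCont thapsigargin replicate 1. With an estimated correlation the adjusted p was 0.275 for it, 0.213 for NFAT targets, 0.348 for sterol biosynthesis and 0.311 for G2/M, so these calls were lost.

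Between siSTIM1 and siCont in GemR 577 genes differed, with counts from 323 (without siSTIM1 vehicle replicate 1) to 1216 (without siCont vehicle replicate 3) and 3499 with the length-slope term, which was built from the same residuals; the other replicates that moved it by over 1.5 times are given in the report. The largest were PDE7B (1.54), ANKRD1 (1.52), LETM2 (1.38), HES1 (1.38), CYP24A1 (1.38) and CDH5 (1.34), and LYPD3 (-2.65), FZD10 (-2.48), RRAD (-2.47), CXCR4 (-2.41), CLDN4 (-2.33) and ABCA1 (-2.24). LETM2 did not pass without siCont vehicle replicate 1 (1.19, adjusted p = 0.0696), siCont thapsigargin replicate 3 (0.0725), siSTIM1 vehicle replicates 1 and 3 (0.0633 and 0.0584) or siSTIM1 thapsigargin replicates 1 and 2 (0.0550 and 0.0582). List medians were 0.25 for PERK-ATF4, 0.17 for ATF6-XBP1, -0.55 for NFAT targets, -0.35 for immediate early genes, -0.11 for epithelial markers, 0.0942 for S phase, -0.24 for p53 targets and -0.0827 for hypoxia and glycolysis. The S phase list (adjusted p = 0.0162) had 0.0803 without siCont thapsigargin replicate 1 and 0.0820 without siSTIM1 thapsigargin replicate 2. With an estimated correlation PERK-ATF4 and p53 kept the call (adjusted p = 0.0469 each). It was lost for ATF6-XBP1 (0.116), NFAT targets (0.136), immediate early genes (0.455), epithelial markers (0.0763), S phase (0.445) and hypoxia and glycolysis (0.0763).

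The response differences ran against each other, and they share the 6 GemR siCont libraries. Their covariance across genes was -0.101, against -0.0351 in 100 simulations of the same libraries with noise alone, a difference of -0.0658. The correlations were -0.55 and -0.50. The simulated noise had 1 spread per gene over all 6 groups. Among the shared libraries, GemR siCont vehicle replicate 1 deviated more from its group (SD 0.297) than any other library, so the difference may be overstated. Of 401 genes called in both, 394 (98.3%) went in opposite directions, 250 higher in GemR and lower with siSTIM1 (27.1 for independent lists) and 144 the other way (15.1). The 3 controls per medium could not be split into parts of 2, so the shared libraries were allowed for by the simulated covariance alone, and the counts for independent lists do not allow for them.

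For the 9 comparisons of 3 against 3 libraries the 10 splits of each are too few for a share under 0.05. The real counts were 5253, 4402, 3187, 5000, 6314, 5496, 4796, 6365 and 7475, and the highest other split gave 18 genes for GemR against Par in vehicle and 0 in each of the other comparisons; the real split was the 1 that gave as many. For the response differences, 6 of 100 drawn splits gave as many as 1938 genes (highest other 7269) and 10 of 100 as many as 577 (highest other 6844), the real split included. The others with as many swapped unequal numbers of libraries in the 2 media, which carries the difference between the lines or siRNAs into the count, a structure of the samples, so this count does not decide whether chance can be excluded. Of the 48 equally swapped splits 0 gave as many (highest 0). In these, and in the other splits of 3 against 3 libraries, the groups mix libraries of different lines, siRNAs or media. Their real differences widen the spread and lower the count, so these low counts do not decide whether chance can be excluded.

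The PERK-ATF4 list responded less in GemR than in Par, with medians of 1.02 and 1.64. Without GemR siCont vehicle replicate 1, a library with a length trend, the median difference was -0.621, which argues against that library as the cause. The size-factor scaling stays open for a shift of all genes together, since the scaling itself holds the median over all tested genes (0.00880) near 0. The higher STIM1 level of GemR cells stays open: with siSTIM1 the list responded more, by a median of 0.25 against the 0.64 it lacked, with 0.227 the lowest over left-out replicates, and 12 of 30 genes passed, but the comparison shares the GemR siCont libraries and the siRNA may act through other genes too, so the STIM1 level and other effects of the siRNA cannot be told apart. For that reason a test first read as favouring STIM1 was set to open, and other differences between the lines were not tested.

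GemR siCont vehicle replicate 1 and GemR siSTIM1 thapsigargin replicate 1 stood apart from their groups. Their deviations fell with transcript length, at Spearman's rho of -0.615 and -0.539 across 12446 genes, as a bias by length such as differing RNA integrity might give, and that of GemR siCont vehicle replicate 3 rose with length (0.565), measured against a group mean that includes replicate 1. Removing the trend took away 17.3% and 12.1% of the standard deviation, and what gave the rest of the spread was not tested. Mixing with RNA of another group is argued against in the first, where the highest implied share was 0.485% (GemR siSTIM1 vehicle not covered), and mixing with RNA of a Par group in the second, at 0.160%. RNA integrity was not given in the sources used here.

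The 18 tested genes from STIM1 to MRPL17 on chromosome 11 were higher in GemR, and in 0% of 1000 shuffled gene orders a run of 10 genes reached the median of the run around STIM1, which argues against chance placement. Runs elsewhere passed the same shuffle with thapsigargin, among others the next higher run (1.4%), while the next higher run in vehicle did not (17.6%). For vehicle runs of lower genes on chromosomes 4, 1 and 12, 0%, 0.1% and 0.2% of shuffles had a highest run as far from 0. The lowest shuffled runs were not taken, so these shares are not the chance of so low a run. Of 5 genes 100 kb to 2 Mb away that were at least 2-fold higher, 4 lay in the stretch and TNNT3 on the other side of STIM1, and the 4 argue against reads of STIM1 and RRM1 counted for their neighbours. A gain of DNA on both sides of the pair is argued against by the share of genes within 1 Mb higher in both media, 15.38%. A candidate explanation is a gain of DNA copies from STIM1 towards the centromere: of 6 genes there too low to be tested, 5 (83.3%) had a higher mean in GemR in both media, near the floor and few, while DNA was not measured and shared regulation was not tested.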

How the results depend on the processing

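The alternatives with GemR siCont vehicle replicate 1 and GemR siSTIM1 thapsigargin replicate 1 left out together (the length-trend pair) and with a length-slope term were chosen after seeing the data; the slopes come from the same residuals as the test, so higher counts under it are not better calls. No named gene or list called in the main fit or under an alternative changed direction, a list's direction being that of its test. Genes and lists called in neither were not checked for direction. Under the other pseudocounts, filters, median-centring, quantile normalization, limma without trend or robust and DESeq2, all 11 counts of genes stayed within 1.5 times. The labels do not say whether same-numbered libraries were handled together. Correlations of same-numbered deviations ran from -0.18 to 0.23, 6 of 21 over 0.1, which with 3 libraries per group does not decide it. With the replicate block all 11 counts were higher, at 5472, 4633, 3283, 5190, 6490, 5753, 4931, 2010, 679, 6504 and 7636. Of the lists, epithelial markers in siSTIM1 vehicle passed with it (adjusted p = 0.0478).

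A 2-fold minimum gave, fewer by construction, 833, 771 and 545 genes for thapsigargin in Par, GemR siCont and GemR siSTIM1, 913 and 1183 for GemR against Par in vehicle and thapsigargin, 662 and 728 for siSTIM1, 438 and 140 for the response differences, and 1466 and 1865 against untreated Par. With only the libraries compared, counts were 2843 (thapsigargin in GemR siCont), 3129 (GemR against Par, vehicle), 3294 (siSTIM1, vehicle) and 317 (siSTIM1 response difference). All 4 include GemR siCont vehicle, whose replicate 1 deviated most from its group (SD 0.297). The other 7 counts changed less, among them the GemR and Par response difference, which includes that group too. Comparisons of single groups all lost equally many libraries, so fewer samples alone do not account for which moved. The main fit pools the spread of all groups, so it may understate this group's error and overstate these counts, which was not tested. The thapsigargin changes of STIM1 (-0.31, adjusted p = 0.0706) and RRM1 (-0.21, 0.0543) in siSTIM1 did not pass with only the libraries compared. On reads of the 17 libraries without siSTIM1 vehicle replicate 3, that STIM1 change was -0.25 (0.160) by edgeR and -0.26 (0.139) by DESeq2. Limma without that library gave -0.27 (0.0880), and the authors' own table has -0.30 (0.0336) for this STIM1 change. On the 17 libraries edgeR gave 346 genes for the siSTIM1 response difference, and RRM1 with siSTIM1 in vehicle was 0.15 (0.0452) by DESeq2. Without a filter RRM1 did not pass for thapsigargin in Par (-0.19, adjusted p = 0.0655) and siSTIM1 (-0.21, 0.0574) or for siSTIM1 with thapsigargin (0.19, 0.0643). By quantile normalization RRM1 with siSTIM1 in vehicle was 0.31 (0.00159). Without the length-trend pair the GemR and Par response difference had 3852 genes and RRM1 with siSTIM1 in vehicle 0.15 (0.0187). The length-slope term gave 5045 genes for thapsigargin in siSTIM1, 3848 and 3499 for the response differences, 0.12 (0.0183) for RRM1 with siSTIM1 in vehicle and -0.39 (0.000341) for the siSTIM1 response difference of STIM1. Where no cause is given, the cause was not tested.

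With an estimated correlation, lists called were 7 of 12 for thapsigargin in siSTIM1, 5 of 8 and 5 of 9 for GemR against Par in vehicle and thapsigargin, 2 of 6 and 2 of 9 for siSTIM1, 2 of 6 and 2 of 8 for the response differences, and 8 of 15 and 3 of 9 against untreated Par. Leaving out each replicate in turn, the GemR and Par response difference ran from 1529 to 2943 genes, that of siSTIM1 from 323 to 1216, and log2 fold changes from -0.21 to -0.17 (RRM1, thapsigargin in Par), -0.25 to -0.16 (RRM1, thapsigargin in siSTIM1), 0.15 to 0.24 (RRM1, siSTIM1 with thapsigargin), -0.41 to -0.22 (STIM1, thapsigargin in siSTIM1) and -0.49 to -0.27 (STIM1, siSTIM1 response difference). Depth limits small differences: genes under a mean of 10 were not tested.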

Other observations

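The follow-ups on the STIM1 site, the lists without the word and the words of genes that rose were chosen only after the result was seen; the word search itself was set beforehand.

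Genes outside the fixed lists also moved with siSTIM1. With thapsigargin, WNT9A stood lower in siSTIM1 than in siCont, at -3.09 ± 0.23 on the log2 scale, and TPRG1 at -3.24 ± 0.28, while AP3B2 stood higher at 3.44 ± 0.20 and the actin-binding gene SYNPO at 2.94 ± 0.27. In vehicle the metallothionein MT1F was at -2.65 ± 0.26, a value that is uncertain because the gene has close paralogs.

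An siRNA lowers transcripts that pair with its seed, and this was tested as a hypothesis by a search of all 7-base words in 3' UTRs for words tied to lower expression with siSTIM1 in both media. The leading word was GAATCTC, with a score of 14.3, the smaller of the absolute t in vehicle (-14.6) and thapsigargin (-14.3). The 95th percentile of the best score over 200 shuffles was 3.96, and the same search of GemR against Par reached 3.28. The overlapping words AATCTCA and TGAATCT followed at 6.73 and 6.42. Words that share no such overlap, AATATTA (5.30), CAATATT (4.97) and AAATATT (4.64), and the search for higher expression (4.58) also passed the highest shuffled score of 4.38, so passing the shuffles alone does not point to a seed. Of 1015 genes with the word 31.0% were lower in vehicle and 37.0% with thapsigargin, against 21.2% and 18.4% of 10685 genes without it. Among the 11700 tested genes with a 3' UTR, the word was in 57 of the 197 (28.9%) called at least 2-fold lower in vehicle. With thapsigargin it was in 92 of 342 (26.9%).

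These values are consistent with a seed effect of the siRNA on part of the lower genes, with the score of 14.3 as the test. SLC7A5 and FOSB held 1 site each, NFATC2 held the word too, and SLC3A2, KRT6A, MMP10 and EGR3 held 0, and the sterol list kept a median of -0.67 in vehicle without its 1 gene with the word, against -0.68 with it. The p53 list with thapsigargin went from -0.38 to -0.13 without MDM2, RRM2B and TNFRSF10B. STIM1 itself held 1 site, in the coding sequence of exon 8 (chromosome 11, 4082220 to 4082226), as 19.7% of 4671 transcripts of like length do. The siRNA sequence is not given in the sources used here, so the link to it was not tested.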
